A study of Bos taurus with 27 samples.

How the data were processed

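RNA was sequenced from 27 cattle (Bos taurus) embryos collected on day 15 of pregnancy, with 1 library per embryo. Per the labels' protocols, libraries were made with a stranded kit that keeps polyadenylated RNA and were read on an Illumina NovaSeq instrument as single reads of 100 bp. STAR, a splice-aware aligner, and featureCounts, which assigns aligned reads to genes, are named in the submitters' processing notes without versions. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. Each deposited file holds the authors' whole-number read count for each of the same 19994 Ensembl cattle gene identifiers, in the same order in all files and without rows for unassigned reads. The counts were not normalised. How reads shared by near-identical gene copies were counted is not stated, so values for members of multicopy families are uncertain.

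The labels give each embryo's maternal diet (omega-3 or omega-6) and a size class (long or short). The titles add a size number, whose unit the labels do not state, a letter m or f, read here as male and female, and an embryo number. This gave 6 long omega-3, 10 short omega-3 and 11 short omega-6 embryos. No long omega-6 embryo was among those analysed here, so size class and diet could be separated only through short embryos or through the size number. Neither dams nor batches are named. Several embryos may come from the same dam, so p-values measure the spread between these embryos. Embryo numbers do not repeat across groups, so no embryos were paired. A chi-square comparison of the counts of all 351 pairs of libraries gave at least 16.9 per degree of freedom (median 86.7), so no library was a copy of another.

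Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were filtered with filterByExpr on the 3 groups (minimum count 10, minimum total 15, minimum proportion 0.7), libraries were scaled by the trimmed mean of M-values (TMM), and the quasi-likelihood F-test (glmQLFit and glmQLFTest) was run two-sided with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. The 3 group comparisons (long against short omega-3, short omega-3 against short omega-6, and long omega-3 against short omega-6) came from a model of group and sex letter over all 27 embryos, in which all groups share the spread estimated per gene. The m against f comparison came from the same model. Diet at equal size and the slope on size came from a model of diet, log2(size number) and sex letter over all 27 embryos, with slopes given as log2 fold change per doubling of the size number. The difference in slope between diets was the interaction term in the 21 short embryos. After filtering, 11919 genes were tested, and 11534 in the model of the 21 short embryos. Standard errors (SE) were taken as the size of the log2 fold change over the square root of F. CPM are counts scaled to a common library size after TMM, and log2 CPM for principal components used a prior count of 2. Correlations and the size difference between diets were tested with 100000 permutations. The agreement of slopes between diets was tested with 100 permutations of size among the omega-6 embryos.

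The test was checked on simulated counts drawn from the embryos' own means and library sizes with 200 changed genes. At a true log2 fold change of 1 it recovered 83.6% of the changed genes in long against short omega-3, 92.5% in the diet comparison of short embryos, 85.1% in long omega-3 against short omega-6, 98.5% for diet at equal size and 97% for m against f. At 0.5 the shares were 35.8%, 58.2%, 29.9%, 65.7% and 59.7%. Of simulated size slopes, 79.1% were recovered at 0.25 per doubling and 97% at 0.5. Slope differences between diets were recovered in 2.99% of genes at 0.25, 38.8% at 0.5 and 84.8% at 1. Between 3.95% and 7.26% of the calls in these simulations were false. Genes were drawn independently of each other, and changes were placed only in genes with a mean log2 CPM of at least 1. Spread that many genes share within an embryo was thus absent. These shares need not hold for the real embryos or for genes with lower counts.

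Alternatives fixed before the data were examined were size factors as in DESeq2 (RLE), no filter on low counts, DESeq2 1.42.0 in place of edgeR, limma 3.58.1 (voom with sample quality weights), models without the sex letter, fits on the compared groups only, fits without the smallest embryo or without each long embryo, and other scales or subsets for the size number. Fits without embryos 22 and 25 and size added to the group model were chosen after seeing the data. So were fits without embryo 07 outside long against short omega-3, and the per-embryo measures set against size.

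Part of the plan could not be run. The files do not pair gene identifiers with names, and the RefSeq gene table used here (assembly ARS-UCD2.0) matched 0 of the 19994 identifiers. The tests of 23 gene lists (609 genes) fixed beforehand, the cell type scores and the genes to be named by symbol are therefore void. The rule for naming genes was the largest positive and negative log2 fold changes among called genes with a mean log2 CPM of at least 1, or, with fewer than 10 calls, the smallest p values. It was kept without its symbol condition and limited to 2 identifiers in each direction per comparison.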

Results

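The series examined how maternal diet affects cattle embryos at day 15 of pregnancy, when the embryo is still free in the uterus and its outer layer lengthens from a sphere to a filament. RNA-seq counts were analysed for 27 single embryos, 16 from dams on an omega-3 diet and 11 from dams on an omega-6 diet. Of the omega-3 embryos, 6 were classed as long, with size numbers of 10.5 to 20.3 (13.3 ± 3.57, SD, n = 6), and 10 as short, with size numbers of 0.4 to 9.5 (4.62 ± 2.99, SD, n = 10). All 11 omega-6 embryos were short, at 1.4 to 7.7 (3.54 ± 1.85, SD, n = 11). The letter m stood in 15 titles and f in 12. Total counts ran from 17931620 to 29868584 per embryo, with a median of 24349563. The total count was unrelated to log2 size (Pearson r = -0.117, permutation p = 0.56, Spearman rho = -0.129, permutation p = 0.52, n = 27; r = 0.0101 without the 2 embryos farthest in size).

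Whether the diets gave embryos of different size was asked first. On the log2 scale omega-3 embryos exceeded omega-6 embryos by 0.83 (2.49 ± 1.47 against 1.66 ± 0.72, SD, n = 16 and 11), a 1.78-fold difference in geometric mean that did not pass a two-sided permutation test (p = 0.0969). On the linear scale the difference of 4.34 (7.88 ± 5.34 against 3.54 ± 1.85) gave p = 0.0144. Among the 21 short embryos the log2 difference was 0.11 (permutation p = 0.837). Keeping short embryos selects on size itself and leaves out the long embryos, all of them omega-3. That value therefore cannot tell whether the diets gave embryos of different size. All of these permutations treat embryos as exchangeable, although the diets were those of dams, which are not named. The p-values thus compare these embryos and do not test the diets over dams.

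Embryos were ordered by size along the first principal component of log2 CPM. This component held 30.5% of the variance and was lower in larger embryos (Pearson r = -0.786, permutation p = 2e-05, adjusted 5e-05; Spearman rho = -0.88, permutation p = 1e-05, adjusted 2.5e-05; n = 27, 5 measures tested). Without the 2 embryos farthest from the median size, r was -0.77. Within the 16 omega-3 embryos r was -0.92 (adjusted permutation p = 1.7e-05), and within the 11 omega-6 embryos it was -0.639 (permutation p = 0.036, adjusted 0.09). For each embryo its own 10 most counted genes were taken, so the set could differ between embryos. Their share of all counts was 12.1% in the smallest embryo and 18.3% in the largest. This share rose with log2 size (Pearson r = 0.866, permutation p = 1e-05, adjusted 5e-05, Spearman rho = 0.853, permutation p = 1e-05, adjusted 2.5e-05, n = 27). It had r = 0.821 without the 2 farthest embryos. Its r was 0.931 within omega-3 and 0.632 within omega-6 (adjusted permutation p = 1.7e-05 and 0.09). A p of 1e-05 is the smallest these permutations can give. The number of genes with a count at equal depth fell with size at r = -0.433 (permutation p = 0.026, adjusted 0.032; rho = -0.384, permutation p = 0.049, adjusted 0.061), but rested on the extremes, since r was -0.229 (permutation p = 0.28) without the 2 farthest embryos. The second component (16.7% of the variance) also fell with size over all embryos (r = -0.507, permutation p = 0.0075, adjusted 0.012; rho = -0.597, permutation p = 0.0013, adjusted 0.0022; r = -0.43 without the 2 farthest) and had r = -0.874 within omega-3 (adjusted permutation p = 1.7e-05) and -0.00615 within omega-6 (adjusted permutation p = 0.99). Without the omega-6 embryos 22 and 25 its r over the other 25 embryos was -0.832 (adjusted permutation p = 1.7e-05; rho = -0.834).

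**Figure D1:**
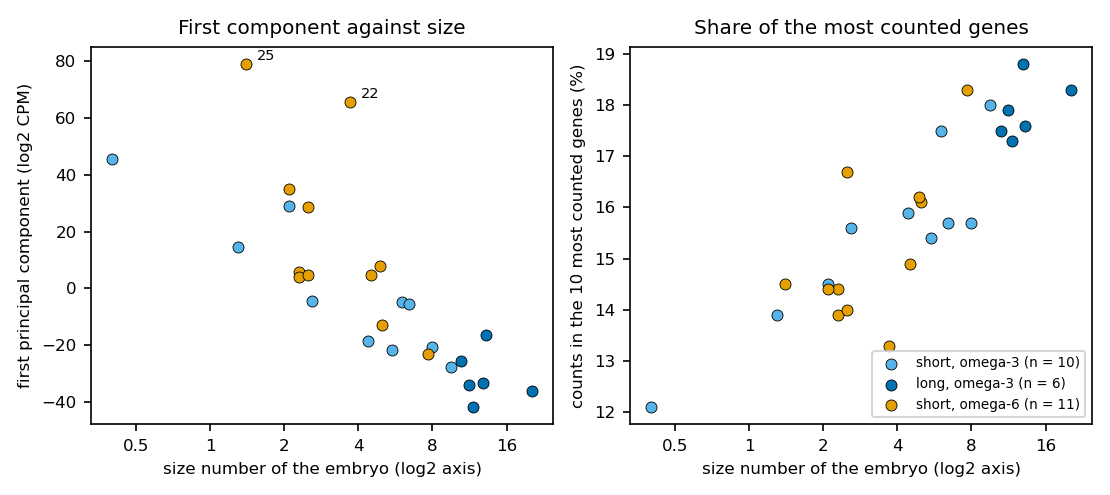
First principal component of log2 CPM (left) and the percentage of counts in each embryo's own 10 most counted genes (right) against the size number on a log2 axis, 1 point per embryo, coloured by group. Both follow size (r = -0.786 and 0.866, n = 27), and the short omega-6 embryos numbered 22 and 25 lie above the rest on the left.

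Genes that followed size were numerous. With diet and sex letter in the model, edgeR's quasi-likelihood test called 3450 of 11919 genes (28.95%), of which 1698 rose and 1752 fell as size increased. Slopes are relative to the other genes, because TMM scaling takes rises and falls to balance. The similar numbers up and down are therefore partly set by the scaling. Without the smallest embryo 2143 genes were called. Most slopes were shallow: their median size was 0.19 log2 units per doubling (1.14-fold), and 217 genes rose and 154 fell by at least 0.5 per doubling. The embryos spanned 5.67 doublings. When the tested genes were ranked by mean count and cut into 3 classes of 3973, 511 genes rose and 761 fell in the most counted class, 626 rose and 463 fell in the middle class, and 561 rose and 528 fell in the least counted class. The median size of the called slopes was 0.13, 0.16 and 0.33 in these classes. Genes with few counts may need steeper slopes to be called, so these medians do not compare the steepness of all genes in the classes.

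The most counted transcripts took part in this change unequally. Here genes were ranked by mean CPM over all embryos, which gives 1 fixed set, unlike the share of each embryo's own 10 genes above. Among the 10 highest, 5 rose and 2 fell with size by the edgeR test. Without the smallest embryo 3 rose and 2 fell. The steepest of the 10, singled out after its values were seen, ranked 3 by mean CPM and rose by 0.97 ± 0.11 (SE) per doubling (adjusted p = 6.15e-07). It held 880 CPM in the smallest embryo and 31800 ± 4030 CPM (SD, n = 6) in long embryos, against 15100 ± 10100 in short omega-3 (n = 10) and 11800 ± 8760 in short omega-6 (n = 11). The gene ranked 2 rose by 0.52 ± 0.11 (SE) per doubling (adjusted p = 0.000521), with 1160 CPM in the smallest embryo and 27000 ± 1780 (SD, n = 6) in long embryos, and its slope was 0.30 without the smallest embryo. The most counted gene of all averaged 51900 CPM, with 39400 CPM in the smallest embryo and 55300 in the largest, and its edgeR slope of 0.03 ± 0.03 (SE) did not pass (adjusted p = 0.544).

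By the fixed rule, the largest positive slope belonged to ENSBTAG00000007687, at 2.08 ± 0.27 (SE) per doubling (edgeR adjusted p = 3.43e-06). It measured 5.92 ± 2.84 CPM in long omega-3 (SD, n = 6), 1.23 ± 2.28 in short omega-3 (n = 10) and 0.42 ± 0.88 in short omega-6 embryos (n = 11), and 19 of the 21 short embryos lay below every long embryo. The steepest fall was that of ENSBTAG00000019801, at -1.36 ± 0.15 (SE) per doubling (adjusted p = 3.51e-07). Its 73.2 CPM in the smallest embryo far exceeded all others, and without that embryo the slope was -1.07 (adjusted p = 0.00552). The next by the rule rested on few embryos. ENSBTAG00000047134 (slope 1.97 ± 0.52, SE, adjusted p = 0.00543) reached 44.9 CPM in long embryo 04 and at most 0.996 CPM in short omega-6 embryos. ENSBTAG00000032642 (slope -1.35 ± 0.34, SE, adjusted p = 0.00386) reached 58.9 CPM in a short omega-3 embryo, had a Spearman rho with size of -0.073, and was not called in the 21 short embryos alone (adjusted p = 0.202).

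**Figure D2:**
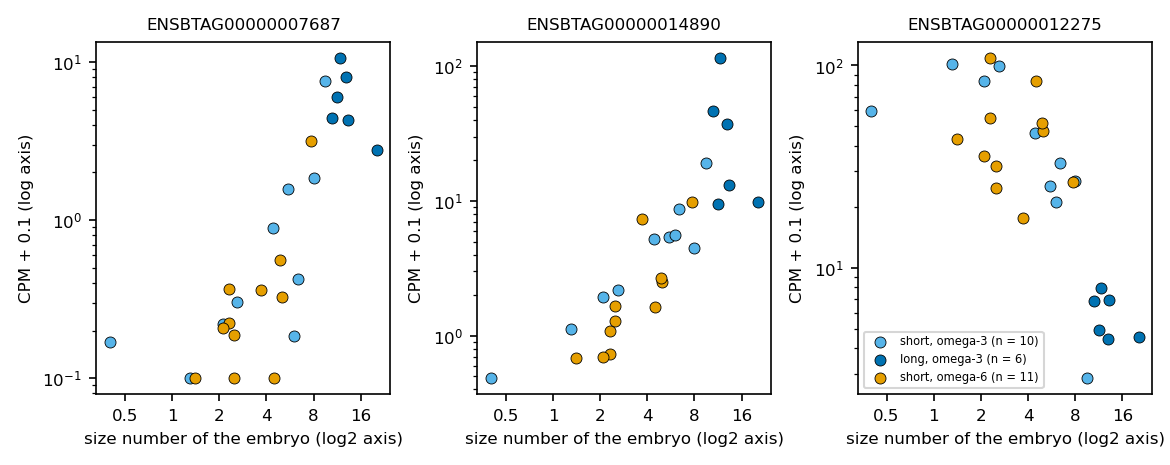
CPM plus 0.1 on a log axis against size number on a log2 axis for 3 named genes, 1 point per embryo, coloured by group. For the genes at left and centre 19 of 21 short embryos lie below every long embryo, and for the gene at right 20 of 21 lie above, the exception being short omega-3 embryo 11 of size 9.5 at 2.75 CPM.

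The size slopes were compared between diets in embryos that no fit shared. Across 11919 genes, slopes fitted in the 16 omega-3 embryos correlated with slopes fitted in the 11 omega-6 embryos at r = 0.609. Genes are not independent replicates, so size was permuted among the omega-6 embryos; the highest of 100 permuted values was 0.545 and the median 0.0415 (p = 0.0099, the smallest these permutations can give). Of the 4348 genes called in the omega-3 embryos, 3625 (83.4%) had the same sign in the omega-6 embryos. There the median slope in the omega-3 direction was 0.18, against 0.15 in the omega-3 embryos, and without embryos 22 and 25 it was 0.14 in the 9 other omega-6 embryos. By itself the omega-6 fit called 1 gene. A test of the slope difference in the 21 short embryos called 0 of 11534 genes with edgeR (505 at an unadjusted p below 0.05, where 577 would come by chance), 8 with DESeq2 and 1 with limma-voom. In simulation this test recovered 38.8% of differences of 0.5 per doubling and 2.99% of differences of 0.25, so most differences of 0.5 or less would be missed.

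Long and short embryos under the same omega-3 diet differed in 169 genes, 114 higher and 55 lower in long embryos (edgeR, adjusted p below 0.05). The balance depended on the method and the embryos: 354 were higher and 339 lower with DESeq2, 745 and 458 with limma-voom, and 520 and 484 with edgeR without embryos 22 and 25. At least 2-fold changes numbered 63 upward and 12 downward. ENSBTAG00000012275 was 8.61-fold lower in long embryos (log2 fold change -3.11 ± 0.54, SE, adjusted p = 0.012), at 5.82 ± 1.48 CPM (SD, n = 6) against 49.9 ± 34.8 in short omega-3 embryos (n = 10) and 47.7 ± 27 in short omega-6 embryos (n = 11). ENSBTAG00000014890 was 6.93-fold higher (2.79 ± 0.67, SE, adjusted p = 0.0425), at 38.2 ± 40.1 CPM against 5.34 ± 5.45 (SD), and followed size across all embryos with a Spearman rho of 0.917. Its call ended without the smallest embryo (adjusted p = 0.0655) and without long embryo 01, 04, 06, 07 or 16 (adjusted p from 0.0534 to 0.167), where its log2 fold change was 2.07 without 16 and stayed between 2.66 and 3 without each of the others. The call of ENSBTAG00000012275 ended without long embryo 04 or 16 (adjusted p = 0.0647 and 0.0554), while its log2 fold change stayed at -3.04 and -3.19. The largest fold changes by the rule were 4.59 ± 1.14 (SE) for ENSBTAG00000047134 and -4.92 ± 1.25 for ENSBTAG00000019801 (edgeR adjusted p = 0.0443 and 0.0478). The first was carried by long embryo 04. The second was enlarged by the smallest embryo, but 18 of the 21 short embryos of both diets lay above every long embryo. Without long embryo 04 the first was 0.58 (adjusted p = 0.81), and its call also ended without 01, 07 or 16 or without the smallest embryo (0.0502 to 0.087), with log2 fold changes of 4.37 to 5.02. The second was -2.81 without the smallest embryo (adjusted p = 0.0825), and its call ended when any of the 6 long embryos was left out (0.0668 to 0.128), with log2 fold changes of -4.63 to -5.5.

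The number of calls between long and short omega-3 embryos depended on single embryos. It was 3 without long embryo 04, 2 without 16, 40 without 01, 41 without 07, 92 without 06, 122 without 10 and 49 without the smallest embryo, and it was 1004 without the omega-6 embryos 22 and 25, which are in neither of the groups compared. With log2 size added to the model 0 genes were called (edgeR, 680 at an unadjusted p below 0.05), and the median size of the change over the 169 genes was 0.51 with a median SE of 0.24, against 0.96 and 0.21 without size in the model.

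Diet was compared within the size class both diets share. Between the 10 short omega-3 and the 11 short omega-6 embryos edgeR called 0 of 11919 genes, with 1059 at an unadjusted p below 0.05, DESeq2 called 2 and limma-voom called 0. These 1059 genes exceeded the 596 that make up 5% of those tested, but 24 of 100 splits of the short embryos, the real one included, gave 1059 or more (highest 3401). Without the smallest embryo there were 1468. With log2 size added in the 21 short embryos, a planned fit, edgeR called 0 of 11534 genes, with 814 at an unadjusted p below 0.05. The 95% interval of the fold change lay within 2-fold either way for 91.46% of genes. The smallest p values upward were those of ENSBTAG00000032642, at 10.9 ± 21.4 CPM in short omega-3 (SD, n = 10) and 0.86 ± 0.55 in short omega-6 (n = 11), and ENSBTAG00000017580, at 7.29 ± 2.69 and 4.49 ± 1.86 CPM. Downward they were those of ENSBTAG00000018073, at 3.24 ± 0.84 and 5.22 ± 1.38 CPM, and ENSBTAG00000018991, at 1.07 ± 0.27 and 1.61 ± 0.25 CPM. None of the 4 passed (edgeR adjusted p = 0.527 for each). The short omega-3 mean of ENSBTAG00000032642 came mostly from embryos 12 and 13 (58.9 and 42.5 CPM), with at most 3.22 CPM in the others.

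Diet at equal size, over all 27 embryos, gave the same count of 0 calls with edgeR, with 1415 genes at an unadjusted p below 0.05, 2 calls with DESeq2 and 0 with limma-voom. As many genes at that level came in 14 of 100 arrangements of the diets, the real one included (highest 2985), and without the smallest embryo the number was 574. Intervals lay within 2-fold for 93.84% of genes. ENSBTAG00000003525 measured 65.1 ± 10.1 CPM in short omega-6 (SD, n = 11), 49.2 ± 8.05 in short omega-3 (n = 10) and 49.4 ± 8.05 in long omega-3 embryos (n = 6), a log2 difference of -0.41 ± 0.10 (SE) that did not pass (edgeR adjusted p = 0.414). ENSBTAG00000000369 differed by 1.77 ± 0.46 (SE) toward omega-3, likewise not passing (adjusted p = 0.414). Without embryos 22 and 25 the counts at an unadjusted p below 0.05 were 252 for diet among short embryos and 527 at equal size. Diet took a median 3.61% of a gene's variance and size 9.06%, each beyond the other terms of the model. A lone term with no effect would take a median 1.84%. Without the same 2 embryos the medians were 1.5% for diet and 13.8% for size (2% for a lone term). Without the smallest embryo they were 2.81% and 6.59% (1.92% for a lone term). The sex letter took 1.08% over all embryos, under 1.84%, so these values are a rough guide and no test of diet.

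Long omega-3 and short omega-6 embryos differ in diet and size class together. In that comparison 2292 genes were called with edgeR, 1067 higher and 1225 lower in long omega-3 embryos, 323 and 147 of them by at least 2-fold. The median size of a called change was 0.55 log2 units. With log2 size in the model 0 genes were called (944 at an unadjusted p below 0.05). The count of 2292 exceeded the 169 calls within omega-3. The difference between the comparisons is the diet contrast among short embryos, which called 0 genes. That contrast had 1059 genes at an unadjusted p below 0.05 and recovered 58.2% of simulated changes of 0.5. A share of diet in the larger count is therefore not excluded.

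Embryos lettered m and f differed in 46 genes, 12 higher in m and 34 higher in f (edgeR, adjusted p below 0.05). All 12 genes higher in m and 2 of those higher in f changed by at least 2-fold. ENSBTAG00000045750 measured 53.7 ± 16.4 CPM in m (SD, n = 15) and 3.48 ± 12 in f embryos (n = 12), with a log2 fold change of 6.40 ± 0.98 (SE, adjusted p = 0.000593). ENSBTAG00000045544 measured 39.7 ± 6.24 and 3.21 ± 11.1 CPM (6.21 ± 0.999, SE, adjusted p = 0.000877). Genes higher in f changed less, as ENSBTAG00000016313 at 5.91 ± 1.91 CPM in f and 2.78 ± 1.02 in m (-1.09 ± 0.20, SE, adjusted p = 0.00345) and ENSBTAG00000031737 at 6.18 ± 1.71 and 3.54 ± 1.47 CPM (-0.87 ± 0.20, SE, adjusted p = 0.0362).

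The embryo labelled f with number 07, a long omega-3 embryo, went against its letter. It held 41.6 CPM of ENSBTAG00000045750 (926 counts) and 38.4 CPM of ENSBTAG00000045544 (855 counts), within the 13.7 to 76.7 and 26.6 to 52.7 CPM of the m embryos, while the other 11 f embryos had at most 4 and 1 counts. Without it 71 genes were called between m and f, 23 higher in m and 48 higher in f, and all 46 genes were among them. The log2 fold changes of ENSBTAG00000045750 and ENSBTAG00000045544 were then 11.1 and 11.7, against 6.40 and 6.21 with it, so the f means above came almost wholly from this embryo. Against counts this near 0 the larger values depend on the prior count and are no bound. Without embryos 22 and 25 the count was 86.

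**Figure D3:**
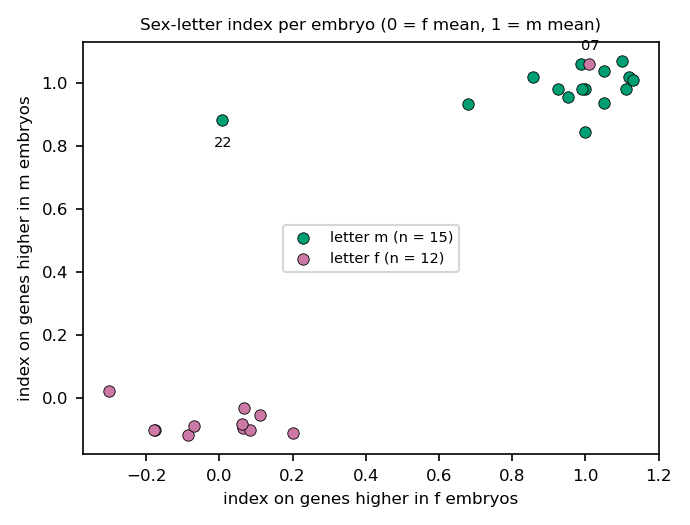
Index of each embryo on genes higher in f (horizontal) and on genes higher in m (vertical), set to 0 at the mean of f embryos and 1 at the mean of m embryos, from genes called without that embryo. The means also leave that embryo out, so embryo 07 is in the f mean of every embryo but itself. The embryo labelled f with number 07 sits among the m embryos at 1.01 and 1.06, and embryo 22 sits apart at 0.00835 and 0.884.

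Embryos 22 and 25, both short omega-6, stood apart from the other 25. Each embryo was set against a fit on diet, size and sex letter made without it and without these 2. Their deviations had SDs of 1 and 0.787 log2 CPM across genes, against 0.325 to 0.63 in the other 25. Deviations over 4-fold numbered 582 genes in embryo 22, 511 of them lower, and 268 in embryo 25, 220 of them lower, against 29 to 186 in the others. Of 1306 genes deviating over 2-fold in both, 1223 (93.6%) went the same way, 1042 down and 181 up. Their median correlation with other embryos was 0.928 and 0.934, their size numbers 3.7 and 1.4 and their letters m and f.

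**Figure D4:**
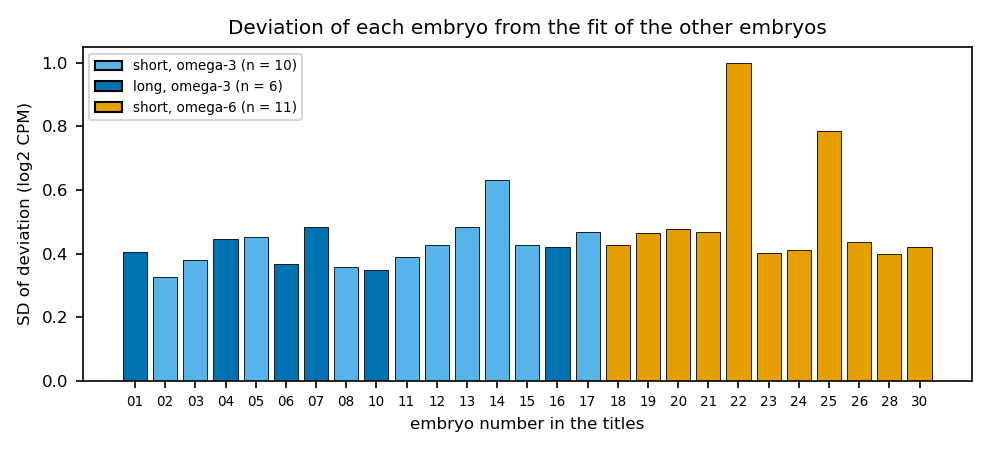
Standard deviation across genes of each embryo's deviation in log2 CPM from a fit on diet, size and sex letter made without it, 1 bar per embryo, coloured by group. Embryos 22 and 25 reach 1 and 0.787, and the smallest embryo, number 14, has the next highest at 0.63.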

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

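The tests of the patterns weighed here were set after their results had been seen. The splits of the samples were likewise described after they had been counted. Among these tests, the fits without the smallest embryo and on unlogged size had been planned, but only as alternatives. In groups of 4 to 10 embryos, 46 sets of values were searched for an embryo far from the others, and 10 held such an embryo. The limit used gives about 1 in 20 only for independent values with a normal spread. Most of these sets are CPM of genes named for large changes or small p values in these same embryos. The 10 of 46 therefore cannot be set against chance.

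Long embryo 01 had the size number 20.3, far above the next at 13.2. Long embryo 04 held 44.8 CPM of ENSBTAG00000047134 while the next long embryo held 0.941. Long embryo 16 held 114 CPM of ENSBTAG00000014890 against 46.2 in the next. Short omega-3 embryo 11, whose size of 9.5 is the highest of the short embryos, held 19.1 CPM of ENSBTAG00000014890 (next 8.66), 7.48 CPM of ENSBTAG00000007687 (next 1.75) and 4.74 CPM of ENSBTAG00000000369 (next 2.2). Short omega-3 embryo 14, the smallest of all, held 73.2 CPM of ENSBTAG00000019801 (next 5.3) and 3.26 CPM of ENSBTAG00000005141 (next 1.46). Long embryo 16, lettered f, held 0 CPM of ENSBTAG00000045750 and 0 CPM of ENSBTAG00000045544, where the lowest of the other 5 long embryos held 41.6 and 37.2 CPM. It stood alone because embryo 07, the other long embryo labelled f, had values like those of m embryos.

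Embryo 07 was weighed as the first pattern. On genes higher in m its index was 1.06 and on genes higher in f 1.01, where 0 is the f mean and 1 the m mean. The m embryos ran from 0.847 to 1.07 on the first and the other f embryos from -0.117 to 0.0245. Genes and means were taken anew without each embryo in turn, so embryo 07 entered the f mean of every other embryo. The index of embryo 07 is thus not on exactly the same scale as these ranges. Male RNA mixed into a female library would leave the index on genes higher in f between 0 and 1, which the value of 1.01 argues against unless female RNA was a minor part (m embryos other than 22 ran from 0.68 to 1.13), and 0 libraries lettered m had a female-like index on both gene sets, which argues against a swap among these 27. A wrong letter, or a library from an m embryo outside this set, remains open and fits the index of 1.06; no biological explanation was tested.

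The second pattern was the distance of embryos 22 and 25 from the rest. Lower depth is excluded, since the lower of their total counts was 24905064 and the other embryos ran from 17931620 to 29868584. The share of each embryo's own 10 most counted genes was at most 14.5% in them and 12.1% to 18.8% in the others. That argues against a few genes taking most of the counts. RNA from another tissue would bring abundant transcripts that the other embryos lack. At most 1 gene reached 10 CPM in either embryo while below 1 CPM in the other 25. A transcript at 1 CPM or more in any of the 25 escapes that count. RNA of a tissue that also reached other embryos is thus not excluded. Their deviations correlated at 0.655 across genes, and the highest value among 300 other pairs was 0.355. Embryos 22 and 25 shared a fit that held neither, while in other pairs each embryo was in its partner's fit. The values are thus not like for like, and a state common to both embryos is only a candidate explanation. Other values set these libraries apart: their TMM factors of 0.773 and 0.888 were the lowest (others 0.964 or more), and embryo 22 had the fewest genes with a count at equal depth (12896, others 13264 or more). Embryo 22, lettered m, had an index of 0.00835 on genes higher in f, like f embryos, but 0.884 on genes higher in m. These leave RNA quality and RNA of another embryo in embryo 22 open. Gene lengths were not used here, so RNA breakdown was not tested, and diet, which both share with 9 embryos that did not deviate, stays open as untested.

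The third pattern was the excess of small unadjusted p values for diet at equal size, 1415 genes where 5% would be 596. Of 100 arrangements of the diets, 14 gave as many, the real one included, and the highest other gave 2985, so the excess is within what chance arrangements give. It fell under 5% without embryos 22 and 25 (527 of 11869 genes) and also without the smallest embryo, an omega-3 embryo (574 of 11878 genes), so it rests on few embryos and cannot be put down to 22 and 25 alone. With the size number not logged it was 647, which leaves open whether the log scale adds to it. An effect of diet too small to call is not excluded.

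Random splits of the embryos were set against each count of calls. For long against short omega-3, 1 of 100 splits, the real one, gave as many as 169 genes, and the highest other gave 16. For the size slope 1 of 100 arrangements gave as many as 3450, the highest other giving 34. For m against f it was 1 of 100, with 46 genes and at most 1 in another split. A share of 1 in 100 is the smallest that these splits can give. They treat embryos as exchangeable although dams are not named. Within that limit, random splits of these embryos did not readily give these 3 counts of calls. For long omega-3 against short omega-6, 2 of 100 splits gave as many as 2292 genes. The other of those gave 4275 genes after moving 10 of the 17 embryos and had put both embryos 22 and 25 with the long group. Whether these 2 embryos account for its count was not tested. The share of 2 in 100 lies under the limit of 0.05 used here, but such a split shows that this count can also be reached without the size class. For the diet comparisons and the slope difference, the real count was 0, which each of the 100 splits must reach, so these splits decide nothing; the highest others were 7 among short embryos, 4 at equal size and 1 for the slope difference. Counted by unadjusted p below 0.05, 24, 14 and 24 of 100 splits gave as many as the real 1059, 1415 and 505 genes, with highest others of 3401, 2985 and 2417, so chance is not excluded for these. By the same measure 36 of 100 splits gave as many as the real 522 genes for m against f (highest other 2610), so there only the called genes stand apart from chance. It was 4 of 100 for the 4302 genes of long omega-3 against short omega-6 (highest other 5475), and 1 of 100, the real one, for long against short omega-3 (2346 genes, highest other 1936) and for the size slope (4718 genes, highest other 2101). The correlation of slopes between diets, 0.609, was reached in 1 of 101 arrangements, the real one, and the highest other was 0.545.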

How the results depend on the processing

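All 4 alternatives for the correlation of slopes between diets stayed between 0.558 and 0.63. None of the named genes changed direction in any alternative fit that gave an adjusted p, the fits on unlogged size left aside. The 4 genes named for long against short omega-3 lost their call in 29 of 58 such fits (ENSBTAG00000019801 in 10 of 14, ENSBTAG00000047134 in 9 of 14, ENSBTAG00000014890 in 7 of 15, ENSBTAG00000012275 in 3 of 15). The 4 named for the size slope lost it in 5 of 40 and the 4 named for m against f in 0 of 28. The 8 genes named for diet had no call to lose and gained none. The size slope stayed within 1.5 times of 3450 genes in 9 of 13 alternatives; it gave 2143 without the smallest embryo (2023 of them shared with the 3450), 1764 in the 21 short embryos and 1 in the 11 omega-6 embryos, where fewer embryos were fitted, and 11 in the 9 omega-6 embryos left without 22 and 25, an alternative chosen after seeing the data. Long against short omega-3 was the least stable: 87 genes without a filter on low counts, 693 with DESeq2, 1203 with limma-voom, 49 without the smallest embryo, and between 2 and 122 with each long embryo left out in turn. Of these, the fit without embryo 07 gave 41. Chosen after seeing the data, fits gave 1004 genes without embryos 22 and 25 (all 169 among them) and 0 with log2 size added. The last also gave 0 for long omega-3 against short omega-6, where limma-voom gave 3930. Size class and log2 size overlap, so the added term takes up part of the same difference. For m against f the count was 77 with DESeq2, 126 with limma-voom, 86 without embryos 22 and 25 and 71 without embryo 07. The diet counts of 0 became 1 without a filter and 2 with DESeq2 among short embryos, and 2 with DESeq2 at equal size. The slope difference gave 1 without a filter, 8 with DESeq2 and 1 with limma-voom. The size difference between diets was 4.34 on the linear scale and then passed its permutation test (p = 0.0144). That test treats embryos as exchangeable although dams are not named. For the differences between tools the cause was not tested. The alternatives planned for the gene list tests and the cell type scores were not run, because no identifier matched a symbol. No paired analysis was possible because embryo numbers do not repeat across groups. Depth limits the lowest genes: 16841 identifiers had a count in some embryo and 11919 passed the filter.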

Other observations

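The tests of the first 2 patterns here were chosen after the patterns had been seen. The prediction for the third was written before its result. All are hypotheses tested on the data they came from.

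Genes that differed between m and f embryos lay close together in the order of the files. Of the 46 genes, 40 fell between rows 798 and 1599, 31 of them higher in f and 9 higher in m, although these rows hold 400 tested genes, 3.36% of those tested. With the files cut into 20 fixed windows of 1000 rows, the boundary at row 1000 parted this stretch, and the fullest window held 26 of the 46 genes and the one before it 14. The highest count in any fixed window over 10000 random draws of as many genes was 12. The 360 tested genes of this stretch that were not called had a median m over f log2 fold change of -0.086, against 0.019 elsewhere. If the files follow an order along chromosomes, these values are consistent with linkage of the sex-dependent genes, with a broad small excess in f embryos along the stretch. The files give no coordinates, so the order was not tested against a map.

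Genes that rose fast with size also had neighbours of their kind. Of the 217 genes rising by at least 0.5 per doubling, 44 had another within 5 rows. The median of 10000 random draws was 24, the 95th percentile 36 and the highest 54. Gene families whose members lie side by side and rise together may explain this. Reads shared between near-identical copies could produce it as well and were not tested.

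Whether expression changes faster at the small or the large end of the size range was tested with a squared term of log2 size. It was called in 3 of 11919 genes over all embryos (edgeR, 854 at an unadjusted p below 0.05) and in 0 genes without the smallest embryo (782 at an unadjusted p below 0.05). Without embryos 22 and 25 the term was called in 7 genes (1241 at an unadjusted p below 0.05), and in 1 when the smallest embryo was left out too (662 at an unadjusted p below 0.05). What curvature this test can detect was not simulated, so weak curvature is not excluded.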
